A study of Homo sapiens with 10 samples.

How the data were processed

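Binding of FLAG-tagged MYC was measured by chromatin immunoprecipitation followed by sequencing with a reference exogenous genome (ChIP-Rx). Per the labels' protocols, cells were induced with 1 µg/mL doxycycline for 24 h or left uninduced and fixed in 1% formaldehyde for 10 min. Mouse cells at 10% were mixed in, and chromatin was sheared to 200 to 500 bp. Libraries were made from 5 ng of DNA with 9 PCR cycles. The labels put 10 libraries in 6 groups. They name the mutants 3A and 7A without saying which residues are changed.

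The submitters' processing notes name cutadapt, Bowtie2, SAMtools, Picard and MACS2, without versions, and the builds hg19, mm10 and hg38, without roles. The authors deposited 1 peak list per induced protein in the narrowPeak layout that MACS2 writes. How the 2 libraries were combined, which control was used and how the mouse reads entered are not given in the sources used here. Each peak has the authors' fold enrichment at its summit, a ratio of IP pileup to local background. It also has the authors' −log10 p-value and −log10 q-value, and a deposited score that is the whole part of 10 times the −log10 q and was not used further. Folds were used to describe and rank peaks within 1 list. Between lists they entered the correlations over shared peaks and the backgrounds recovered from them, the correlation with 3A also being set against permutation within 20 groups of similar background, and levels were not compared between proteins. No spike-in scaling was done here. The lowest −log10 q was 1.32 in the WT list, 1.51 in 3A and 3.81 in 7A, and 0.821%, 3.43% and 1.56% of peaks lay under 5.

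The build was settled from the data: 60.2% of WT summits lay within 1 kb of an end of a protein-coding gene of GRCh38.p14, against 4.59 to 5.96% after shifts of 100 or 500 kb in either direction. Gene names and spans came from a RefSeq table of 59792 genes, without strand, exons or sequence. Distance to a transcription start, as first designed, was replaced by distance to either end of the gene span, so promoters and 3′ ends are not told apart. A summit at a start inside a span can count as away from gene ends. Exon, intron and UTR classes, E-box and other motif counts, and a background of genes with CpG-rich starts were not analysed here.

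Coordinates were counted from 1. A peak was shared if it overlapped another by at least 1 bp. Overlap was tested by placing peaks at random 1000 times, fold ranks by 100000 permutations of the difference in medians, and location and gene lists by two-sided Fisher exact tests. Gene list p-values were adjusted by Benjamini-Hochberg at a threshold of 0.05, over 20 lists, or over the 18 with a WT-bound gene for the test of genes kept in 3A. Keeping within ranges of WT fold was tested by a Cochran-Mantel-Haenszel chi-square test. Odds ratios have 0.5 added to each cell, and shares have Wilson 95% intervals. Of 700 listed symbols 699 matched the table. Genes that share a bidirectional end count as separate genes.

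The gene lists and the rule for named items were fixed before the data were examined: the 10 peaks with the highest fold in each list, among WT peaks without 3A, 3A peaks without WT, 7A peaks without WT and 7A peaks in all lists; up to 4 bound members with the highest WT fold for each list past its test and each background list with a hit; and MYC, MAX, NCL, NPM1, ODC1, CAD, CDK4, LDHA, PER1 and CDKN1A. A peak away from gene ends is named by the nearest protein-coding gene, which need not be its target.

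The whole IP pileup and the local background at each summit were recovered from the fold and p, taking the fold as (pileup + 1)/(background + 1) and p as a Poisson tail. The recovered p matched within 0.02 of the step between neighbouring pileups for 4749 of 4749 WT, 845 of 845 3A and 63 of 64 7A peaks, the exception being the mitochondrial peak. Tested on 2000 simulated peaks, 844 of them with a −log10 p above 300, the recovery returned 100% of pileups. On simulated lists, 600 of 600 written-in overlaps were found among 845 peaks. A gene list given raised binding and raised keeping was called in 20 of 20 draws of each test. Over those draws other lists were called 0 times for binding and 1 time for keeping. Each gene was drawn independently, so the draws do not cover genes that share ends or differ in activity. Alternatives covered the overlap rule, −log10 q of at least 5 or 10, windows of 500 bp and 5 kb, the random placement, merging of peaks within 1 kb, ranking by q, and stratification by WT fold. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, mpmath 1.4.1 and matplotlib 3.10.9.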

Results

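Chromatin binding of MYC, a transcription factor that pairs with MAX, was measured in U2OS cells, a human osteosarcoma line, from which the endogenous MYC gene had been knocked out. The cells carried a doxycycline-inducible, FLAG-tagged MYC that was either wild type (WT) or a mutant named 3A or 7A, and bound DNA was recovered with an antibody to FLAG. Mouse NIH3T3 fibroblasts were added at 10% as a reference genome. The 10 libraries fall into 6 groups. Induced WT, 3A and 7A immunoprecipitates (IPs) and uninduced WT IPs have 2 libraries each, and induced and uninduced WT inputs have 1 each. The comparisons rest on 3 deposited peak lists. How the 2 IP libraries of an induced protein entered its list is not given, and each protein has 1 list. There are therefore no replicate lists, no spread between replicates, and no test of 1 protein against another across replicates. Intervals and p-values below describe counting error or the arrangement of peaks within these lists. The uninduced IPs and the inputs had no peak list used here, so no peak could be set against the uninduced level. Read totals per library were not used here. Coordinates are hg38, and fold enrichments are the authors' own values for each peak over its local background.

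The first question was how much of the genome each MYC protein occupied. WT MYC had 4749 peaks (exact Poisson 95% interval 4615 to 4886), 3A had 845 (789 to 904) and 7A had 64 (49.3 to 81.7). The WT list was 5.62 times as long as the 3A list and 74.2 times as long as the 7A list. WT peaks covered 4173 kb with a median width of 790 bp, 3A peaks 521 kb with 572 bp, and 7A peaks 33.4 kb with 494 bp. The median of the authors' fold enrichment was 5.15 in the WT list, 3.41 in the 3A list and 3.39 in the 7A list, each relative to its own background. The intervals cover counting error only. The 7A list fell to 39 peaks at a −log10 q of at least 10, where WT kept 4432 and 3A kept 578.

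The strongest WT peaks lay both at protein-coding gene ends and away from them. The highest WT fold, 30.5, was inside PPRC1, a coactivator gene linked to mitochondrial biogenesis, at chromosome 10, 102132700 to 102134098. A peak with a fold of 29.6 on chromosome 7, 4641464 to 4642590, was 40210 bp from FOXK1 and outside any protein-coding gene. NME1, a nucleoside diphosphate kinase gene, had a fold of 28.9 with its summit 7 bp from the gene end (chromosome 17, 51153209 to 51154383), and a second peak inside the neighbouring NME2 had a fold of 22.8. NCL, which encodes the nucleolar protein nucleolin, had a fold of 27.0 (chromosome 2, 231463429 to 231465233). The other leading peaks lay 19930 bp from TCF3 (28.4), 7491 bp from MYO1G (26.0), at YDJC (24.5), inside ING5 (24.1) and 399 bp from SLC33A2 (23.5). Of the 10 WT peaks with the highest fold, the TCF3 peak alone had no 3A counterpart, and none had a 7A counterpart.

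The second comparison asked how far the mutant peaks overlapped the WT peaks. Most 3A peaks overlapped a WT peak by at least 1 bp: 733 of 845, or 86.8% (Wilson 95% interval 84.3 to 88.9%). Peaks moved to random places on their own chromosomes gave a mean of 2.60 overlaps and a maximum of 10 in 1000 draws (one-sided permutation p = 0.001, the smallest the draws can give). Moved to the same offset from random gene ends, they gave a mean of 47.7 and a maximum of 74. For 7A, 49 of 64 peaks (76.6%, 64.9 to 85.3%) overlapped a WT peak against a mean of 0.169 under random placement, and 49 of 64 overlapped a 3A peak against 0.028, with the same permutation p. Placement by gene ends gave 7A means of 2.01 with WT and 0.379 with 3A. Neither placement kept to open or active regions. The tests therefore do not tell shared MYC binding from other signal common to lists from the same cells. In all, 43 of the 7A peaks had both a WT and a 3A counterpart. Seen from WT, 717 of 4749 peaks (15.1%, 14.1 to 16.1%) had a 3A peak and 49 (1.03%, 0.781 to 1.36%) had a 7A peak, while 4026 had neither. Requiring at least 50% of both peaks to overlap lowered the 3A share to 61.4%, with the same permutation p.

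**Figure D1:**
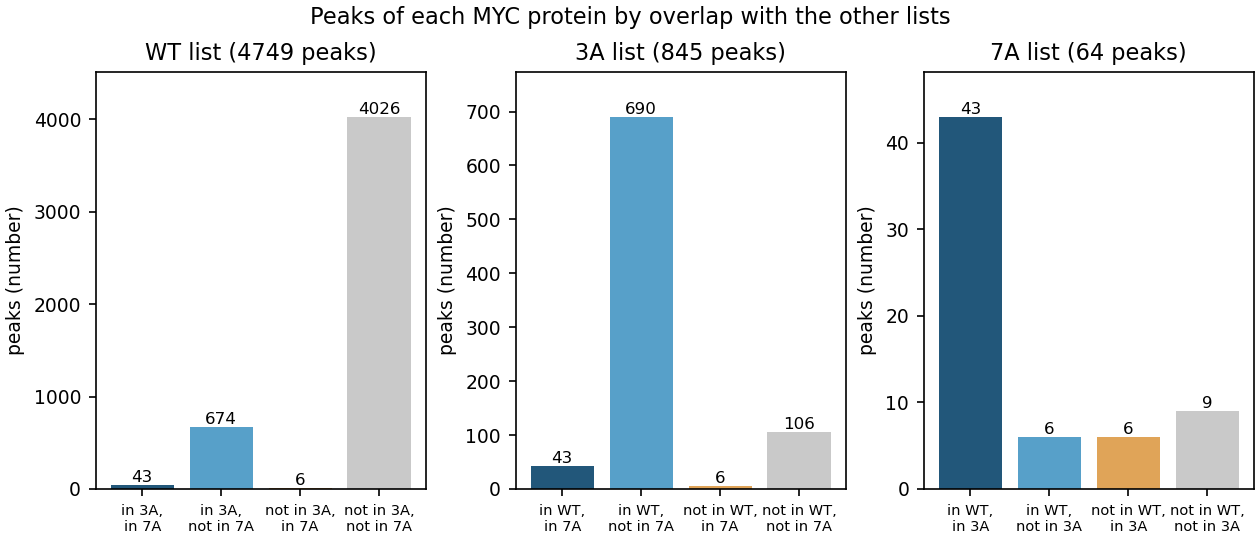
Number of peaks in each MYC protein's list (vertical axes, which differ between panels) by whether they overlap a peak of the other lists by at least 1 bp. Of the WT peaks 4026 overlap neither mutant list, whereas 690 of the 845 3A peaks overlap WT alone and 43 of the 64 7A peaks overlap both other lists.

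WT peaks that 3A also bound were stronger in the WT list. Their median WT fold was 6.69 (quartiles 4.80 to 9.21) against 4.99 (4.08 to 6.37) for WT peaks without a 3A peak, a difference of 1.70 (two-sided permutation p = 1e-05, the smallest that 100000 permutations can give). The probability that a shared peak ranked above an unshared one (AUC) was 0.673. With the WT list split by fold into 10 groups of equal size, 8.63% of the group with the lowest folds had a 3A peak (Wilson 95% interval 6.43 to 11.5%), and 39.2% (34.9 to 43.6%) of the group with the highest. Of the 100 strongest WT peaks 59 had a 3A peak. Strong WT sites without a 3A peak were common as well, since of the 845 WT peaks with the highest fold 288 (34.1%) had one. Across the 733 3A peaks that overlapped WT, the 3A and WT folds correlated with r = 0.523 and rho = 0.513 (permutation p = 0.0001 for each, the smallest that 10000 permutations can give, and r = 0.515 without the 2 peaks farthest from the median WT fold). Both folds are divided by similar local backgrounds, which alone correlates them. With 3A folds permuted only among peaks of similar background, a test chosen after the data were seen, the mean r was 0.132 (maximum 0.269) and the mean rho 0.198 (maximum 0.324), below the observed values (one-sided permutation p = 0.0001 for each, the smallest possible). Both are correlations across peaks, which are not independent replicates. For 7A, WT peaks with a counterpart had a median WT fold of 5.60 against 5.14, a difference that did not pass the test (permutation p = 0.155, AUC 0.609). It did pass under 2 alternatives set in advance, with peaks ranked by −log10 q (AUC 0.719, permutation p = 1e-05, the smallest possible) and with summits within 100 bp counted as shared (AUC 0.645, permutation p = 0.0111). It did not pass under the others set in advance, at a −log10 q of at least 5 (AUC 0.603, permutation p = 0.226) or at least 10 (AUC 0.59, permutation p = 0.57). It also passed when the AUC itself was tested, an alternative chosen after the data were seen (permutation p = 0.0063). Across those 49 peaks r was 0.059 (permutation p = 0.689) and rho 0.106 (permutation p = 0.472).

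**Figure D2:**
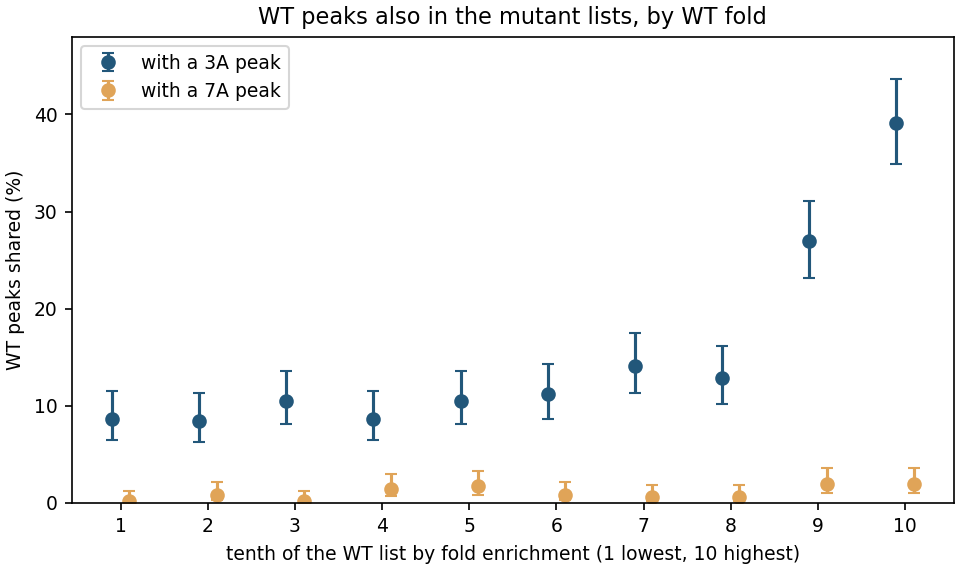
Percentage of WT peaks that overlap a 3A or a 7A peak (vertical axis) in 10 groups of equal size of the WT list ordered by WT fold enrichment (horizontal axis), with Wilson 95% intervals as bars. The 3A share is 8.63% in the lowest group and 39.2% in the highest, and the 7A share is at most 1.89% in every group.

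The highest folds of the 3A list were 8.15 at a site 76620 bp from METTL9, 8.00 at the site near FOXK1 and 7.86 at the site near MYO1G. RPL5 (7.60), ING5 (7.34), RPL27 (7.30), SLC33A2 (7.23), RPL36 (7.16), LOC124904958 (6.91) and a site shared by the ends of ASPRV1 and PCBP1 (6.75) followed, and all 10 overlapped a WT peak.

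The WT sites with the highest folds that had no 3A peak included both gene ends and sites within genes. After the peak near TCF3 they were inside ADGRB1 (fold 21.5), PALD1 (20.6) and HID1 (20.3), 29275 bp from RTN4R (18.3), at SLC16A6 (18.1), inside SLC19A1, a folate carrier gene (17.9), and at the galactosyltransferase genes B4GALT2 (17.8) and B3GALT6 (17.8) and the potassium channel gene KCNQ5 (17.7). In the other direction, 112 3A peaks had no WT peak. The highest folds among them were 5.59 at SEC13, a gene of the COPII coat and the nuclear pore (chromosome 3, 10320877 to 10321247), 5.35 at a site 428677 bp from SPRY1 and 5.24 at a site 65501 bp from GPC1. Others lay inside TRPM8 (4.84) and GALNT7 (4.37), at the end of ARMCX5 (4.58), and near APCS, EDIL3, LPCAT1 and C20orf204 (4.18 to 4.50).

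The third comparison concerned position. The gene table used here gives the span of each gene without its strand, so distance was taken to the nearer end of a protein-coding gene. Transcription starts inside a span were not seen. Of WT summits 60.2% (58.8 to 61.5%) lay within 1 kb of such an end, of 3A summits 69.0% (65.8 to 72.0%), and of 7A summits 34.4% (23.9 to 46.6%), where WT summits moved by 100 kb gave 5.61%. WT peaks with a 3A peak were more often near a gene end than those without, at 71.4% against 58.2% (odds ratio 1.79, 95% interval 1.51 to 2.13, two-sided Fisher p = 1.27e-11). WT peaks with a 7A peak were less often there, at 38.8% against 60.4% (odds ratio 0.42, 0.237 to 0.743, Fisher p = 0.00299). With a window of 500 bp the 7A difference no longer passed (odds ratio 0.61, Fisher p = 0.0867). Of the 7A summits 29.7% were not within 50 kb of a gene end, against 9.62% for WT and 8.05% for 3A. The 7A share counts the mitochondrial peak, which had no measured distance.

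The fourth comparison took 20 gene lists. They share members, so their results are not independent. Canonical MYC targets have 5 genes in common with the nucleolar list, 4 with nucleotide synthesis, 3 each with translation factors and G1/S, and others with further lists. WT MYC had a summit within 1 kb of an end of 3352 of 19974 protein-coding genes (16.8%), and 11 lists exceeded this share after Benjamini-Hochberg adjustment. Each list was set against all other protein-coding genes, active in these cells or not. No background matched for expression or CpG-rich starts was run. The tests therefore do not separate a preference for these lists from binding at active genes in general, here and in the tests against all genes below. Canonical MYC targets were bound at 26 of 30 genes (86.7%, odds ratio 29.4, Fisher adjusted p = 5.87e-16). With a window of 500 bp their odds ratio was 12.2, below 24.4 for cytosolic ribosomal protein genes and 16.99 for nucleolar ribosome biogenesis genes. NME1 (WT fold 28.9), NCL (27.0), CAD, the gene of the first enzymes of pyrimidine synthesis (17.5), and DKC1, a component of pseudouridine-forming particles (14.2), were the strongest. Cytosolic ribosomal protein genes followed with 66 of 79 (83.5%, Fisher adjusted p = 2.12e-37), led by RPL5 (15.6), RPL27 (13.4), RPL36 (12.5) and RPL36A (11.8). Nucleolar ribosome biogenesis genes were bound at 48 of 60 (80.0%, Fisher adjusted p = 7.80e-26), with RRP9 (14.2) and GAR1 (13.9) after NCL and DKC1. Chaperone genes were bound at 17 of 23 (Fisher adjusted p = 7.72e-09), with CCT2 (10.5) and TRAP1 (9.88) highest and HSPD1 and HSPE1 sharing a peak (9.32). Translation factor genes were bound at 31 of 43 (Fisher adjusted p = 7.73e-15), among them EEF1B2 (12.1), EIF3B (11.2) and EIF3D (10.3).

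Splicing genes were bound at 24 of 36 (Fisher adjusted p = 1.44e-10), including SNRPD1 (14.5) and SF3B3 (11.5), and nucleotide synthesis genes at 20 of 32 (adjusted p = 2.43e-08), including PPAT (11.2), which encodes the committed step of purine synthesis. Aminoacyl-tRNA synthetase genes were bound at 11 of 20 (Fisher adjusted p = 0.000247), led by IARS1 (13.2) and YARS1 (9.72), and glycolysis genes at 10 of 21 (adjusted p = 0.0017), led by HK2 (19.5) and SLC16A1 (10.7). G1/S genes were bound at 13 of 31 (Fisher adjusted p = 0.00152), led by CCNE2 (7.45) and CDK4 (6.69), and mitochondrial ribosomal protein genes at 31 of 78 (adjusted p = 4.40e-06), led by MRPL3 (13.6). The G1/S odds ratio of 3.63 rose to 7.64 with a window of 5 kb (Fisher adjusted p = 8.03e-08) and fell to 2.25 with 500 bp, where the list did not pass (adjusted p = 0.0944). Replication-dependent histone genes (0 of 50, Fisher adjusted p = 0.000365) and liver-restricted genes (0 of 30, adjusted p = 0.00949) were bound less often than other genes. Neighbouring histone genes were counted as independent in that p-value. The lists of the MYC and MLX network (6 of 18), circadian clock genes (6 of 18), lysosome and autophagy genes (6 of 33), CDK inhibitors and MIZ1-linked genes (4 of 19), bone and mesenchymal genes (2 of 25), neuron-restricted genes (2 of 30) and keratinocyte and blood cell genes (1 of 23) did not pass, with Fisher adjusted p from 0.138 to 0.816. The hits in the last 2 were GABRB2 (4.91), NEFL (3.71) and CD8A (6.19).

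3A had a summit at 701 genes, and 630 of the 3352 WT-bound genes (18.8%) were also bound by 3A. Cytosolic ribosomal protein genes stood out among them: 42 of the 66 bound by WT were also bound by 3A (63.6%, Wilson 95% interval 51.6 to 74.2%), against 17.9% of other WT-bound genes (odds ratio 7.95, 4.80 to 13.2, Fisher adjusted p = 1.19e-14 over 18 lists). RPL5, RPL27, RPL36 and RPL36A were all among them, with 3A folds of 7.60, 7.30, 7.16 and 5.79 in the 3A list. In a Cochran-Mantel-Haenszel chi-square test stratified by 4 ranges of WT fold the common odds ratio was 6.98 (3.94 to 12.4, adjusted p = 9.85e-12). Of chaperone genes 8 of 17 were kept, of splicing genes 10 of 24, and of translation factor and mitochondrial ribosomal protein genes 12 of 31 each (Fisher adjusted p = 0.0324 for each of these 4 lists). None of these 4 passed the chi-square test stratified by WT fold (adjusted p = 0.0931 for splicing and mitochondrial ribosomal protein genes and 0.139 for chaperones and translation factors), although their odds ratios changed little and the 95% intervals stayed above 1. Stratified by WT fold and local background together, the odds ratios were 2.02 to 3.26, and the intervals included 1 for splicing (0.897 to 5.92), mitochondrial ribosomal protein (0.909 to 4.50) and chaperone genes (0.975 to 10.9). The odds ratio before and after stratifying by WT fold alone was 3.90 (1.54 to 9.88) and 3.89 (1.29 to 11.7) for chaperones, and 3.16 (1.42 to 7.03) and 3.30 (1.34 to 8.10) for splicing genes. It was 2.80 (1.37 to 5.73) and 2.72 (1.26 to 5.88) for mitochondrial ribosomal protein genes, and 2.80 (1.37 to 5.73) and 2.49 (1.13 to 5.49) for translation factors. Canonical MYC targets were kept at 10 of 26 (Fisher adjusted p = 0.0579) and nucleolar ribosome biogenesis genes at 14 of 48 (adjusted p = 0.233). Against all protein-coding genes 8 lists were bound by 3A more often and none less often. They were the ribosomal protein (43 of 79), chaperone (9 of 23), canonical target (10 of 30), splicing (11 of 36), translation factor (12 of 43), nucleolar (15 of 60), glycolysis (4 of 21) and mitochondrial ribosomal protein (13 of 78) lists. The glycolysis odds ratio of 7.10 was 2.25 with a window of 500 bp, 5.20 at a −log10 q of at least 10 and 6.44 with 1 gene per summit, an alternative chosen after the data were seen. The list did not pass in any of these (Fisher adjusted p = 0.698, 0.164 and 0.0529).

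**Figure D3:**
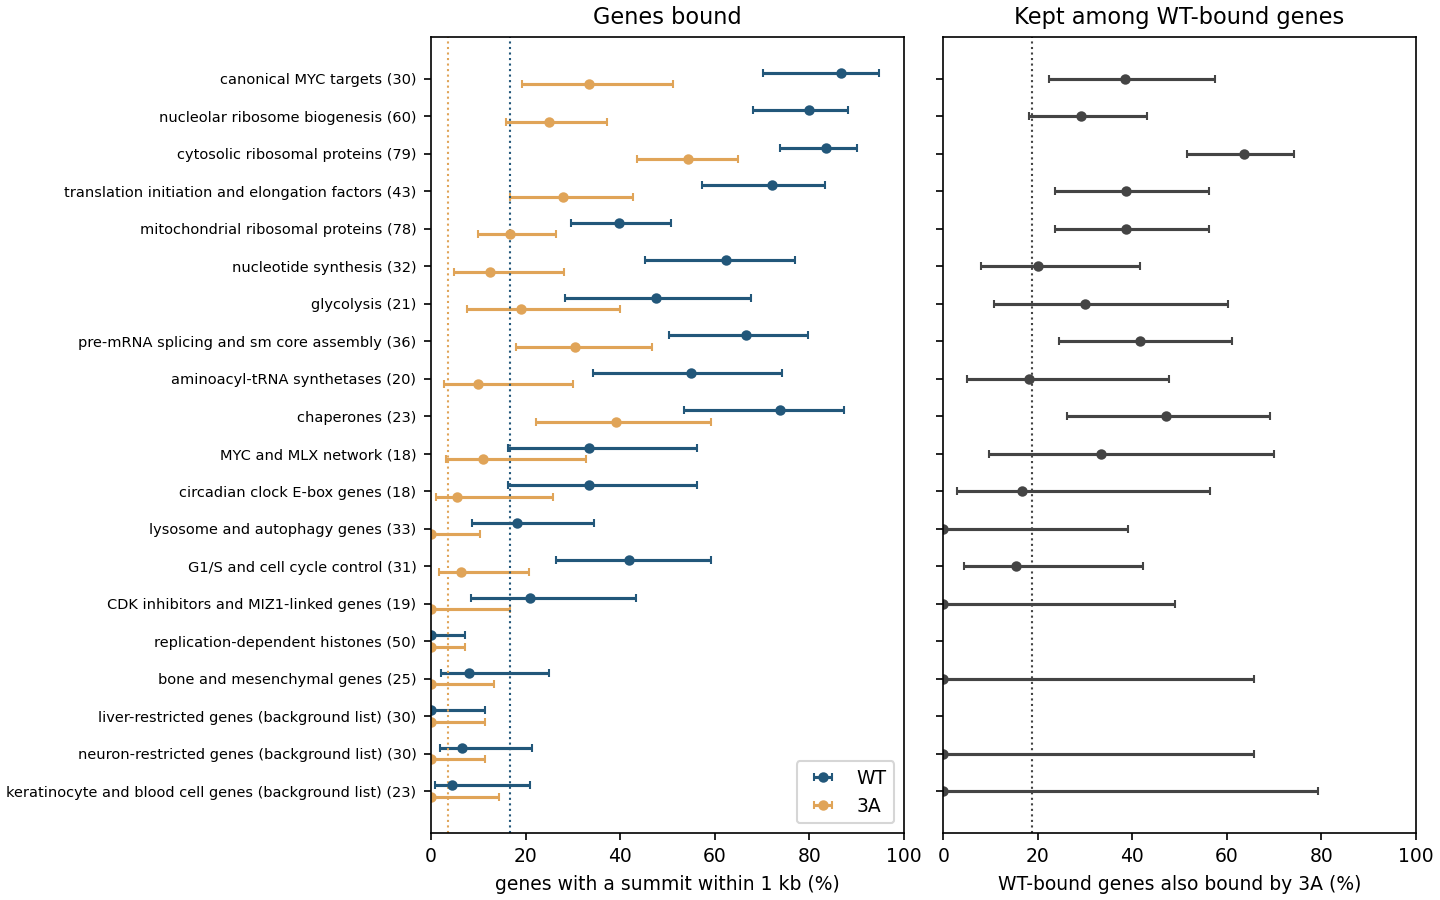
Left, percentage of each list's genes with a WT or a 3A summit within 1 kb of a gene end; right, percentage of the list's WT-bound genes that 3A also bound, with Wilson 95% intervals as bars, the number of genes in parentheses and dotted lines at the shares over all genes (16.8% WT, 3.51% 3A and 18.8% kept). The cytosolic ribosomal protein list has the highest kept share, 63.6%, and lists with no WT-bound gene have no point on the right.

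Of 10 single genes fixed in advance, some were kept by 3A and others were not. NCL, ODC1, the ornithine decarboxylase gene, and CDK4 had a peak at the gene end in both lists, with WT folds of 27.0, 12.8 and 6.69 and 3A folds of 3.29, 3.02 and 3.12 in their own lists. NPM1, the nucleophosmin gene, had its summit 1452 bp inside the gene with a WT fold of 20.1 and a 3A fold of 6.20, so it lies outside the 1 kb rule. MAX (8.70), CAD (17.5) and LDHA (8.18) had a WT peak at the gene end, and the nearest 3A summits were 372786, 126734 and 72190 bp away. MYC, PER1 and CDKN1A had no summit within 1 kb in any list, and the WT peak nearest to MYC was 51611 bp away (fold 14.3). None of the 10 genes had a 7A peak within 1 kb.

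The 7A list was described peak by peak. Of its 64 peaks 22 lay within 1 kb of 25 protein-coding genes. The 20 lists were tested as for the other proteins, as planned for 20 or more bound genes, though after the ribosomal protein count had been seen. Cytosolic ribosomal protein genes were bound more often than other genes, at 5 of 79, namely RPL10A, RPL27, RPL32, RPL37 and RPL37A (odds ratio 71.6, 95% interval 27.2 to 189, Fisher adjusted p = 8.50e-07). Among WT-bound genes they were also bound by 7A more often than others (5 of 66, odds ratio 17.7, Fisher adjusted p = 0.000729). Splicing genes passed against all genes with 2 of 36, SNRPB and SF3B3 (odds ratio 61.4, 15.98 to 236, Fisher adjusted p = 0.00923), but not among WT-bound genes, where the odds ratio was 18.9 (Fisher p = 0.0095, adjusted p = 0.0855). They did not pass at a −log10 q of at least 10 or without chromosomes 20 and 22, where 1 gene was left (odds ratios 73.2 and 38.4, Fisher adjusted p = 0.214 and 0.265). CCT7 was the single bound chaperone gene (Fisher adjusted p = 0.189), and the other 17 lists had none. The highest 7A folds were 4.99 at a site 30759 bp from SCARB1, 4.60 near EDIL3, 4.41 inside TENM2 and 4.38 inside SVIL, followed by RPL27 (4.33), RCOR3 (4.31) and sites 143711 bp from CCND1 and 23486 bp from CCN1 (4.29 each). The next were 433824 bp from MYC (4.17), at MTF2 (4.16), inside AXL (4.16) and near ONECUT3 (4.14). All of these but EDIL3 and SVIL were in both other lists. Of the 15 7A peaks without a WT peak 6 had a 3A peak, among them sites near EDIL3, LIF (3.27) and CHD2 (3.23), inside SLC2A1 (4.05) and at RAB5C (4.00). Sites near ROBO1 (4.09), NLN (3.90) and CCN4 (3.59), inside SVIL, and at RGS5 (3.13) were in the 7A list alone. A further 7A peak lay on the mitochondrial chromosome, with a fold of 1.41.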

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

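Alternatives without chromosomes 20 and 22, within ranges of background, with the AUC as the tested statistic, with 1 gene per summit and stratified by background, the 500 bp window for the 7A gene lists, the placement by gene ends for 7A with 3A peaks, and the permutation of folds among peaks of similar background were chosen after the data were seen. No paired analysis was possible because each protein has 1 list for 2 libraries, and no library could be left out for the same reason. Motif and CpG alternatives were not run for want of a genome sequence. The overlap shares kept their side of the threshold under each alternative run, from 61.4 to 90.0% for 3A with WT, 56.3 to 84.6% for 7A with WT and 60.9 to 87.2% for 7A with 3A. The 3A rank (AUC 0.673 to 0.777) and location (odds ratio 1.57 to 1.89) results also stayed past it.

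At a −log10 q of at least 10 the 7A list had 39 peaks covering 20.5 kb, with 11 near a gene end, since fewer peaks were left. The 7A rank passed its test by q (AUC 0.719), with summits within 100 bp (0.645), without chromosomes 20 and 22 (0.628), within ranges of background (0.669) and with the AUC tested (0.609), and did not pass at a −log10 q of at least 5 (0.603) or 10 (0.59); the cause was not tested. The 7A location odds ratio of 0.61 with a 500 bp window did not pass; the cause was not tested.

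The 5 lists kept more often in 3A became 1 with a 500 bp window, 3 at a −log10 q of at least 10, 2 without chromosomes 20 and 22, 2 with 1 gene per summit, 1 stratified by WT fold and 1 stratified by fold and background; the cause was not tested. The odds ratios of the 4 lists besides ribosomal proteins were 2.80 to 3.90 as reported, 2.57 to 4.27 with a 500 bp window, 2.49 to 3.89 stratified by fold, 2.02 to 3.26 stratified by fold and background, and 2.02 to 5.54 over all alternatives. Cytosolic ribosomal proteins passed in each of these. For single gene lists and the correlation of 3A and WT folds 151 of the values kept their side of the threshold, and 28 in the same direction no longer passed. Most of these were for the translation factor, mitochondrial ribosomal protein, splicing and chaperone genes kept in 3A, and the others were for G1/S genes in WT and glycolysis genes in 3A and splicing genes in 7A. The 2 lists bound more often by 7A became 1 at a −log10 q of at least 10 and 1 without chromosomes 20 and 22, where 1 of the 2 splicing genes was left. Depth per library was not used here, so weak sites missing from the 3A and 7A lists are undetected, not unbound.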

Other observations

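The tests of gene families, chromosomes, recovered backgrounds, depth and q-value threshold were chosen after the data were seen. The tests of an even loss and of stratification for ribosomal protein genes had their criteria written before their results, though the detection threshold of the even-loss model was not fixed in them. Beyond protein-coding genes, WT MYC bound small nucleolar RNA host genes, non-coding genes whose introns carry snoRNAs, at 19 of 29 (65.5%, against 2.95% of other genes not classed as protein-coding, Fisher p = 1.53e-22, adjusted over 17 families p = 1.30e-21). That comparison group took every other gene type together, also for the tRNA, snoRNA and microRNA families, and was not matched for expression. SNHG15 had the highest WT fold (26.0), followed by SNHG17 (19.6), SNHG26 (16.7) and SNHG7 (15.8), and all of these were in the 3A list. The SNHG15 peak is the one named above by MYO1G (3A fold 7.86), and the SNHG17 peak in 3A is the one named by LOC124904958 (6.91). Of the 19, 10 were kept in 3A (Fisher adjusted p = 0.0033). The peak with a fold of 14.3 that is nearest to MYC lay at PVT1, a non-coding gene beside it, and was not in the 3A list. tRNA genes were bound at 59 of 443 (13.3%, against 2.88%, Fisher adjusted p = 5.78e-21), with 5 kept in 3A. snoRNA genes themselves were bound at 30 of 1196 (2.51%), and 15 of the 30 were kept in 3A (Fisher adjusted p = 0.000466). Genes near the same summit were counted separately, so these p-values take neighbouring tRNA or snoRNA genes as independent. The snoRNA genes were not separated from the host genes that carry them.

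Among protein-coding families, mitochondrial import genes were bound at 16 of 25 (Fisher adjusted p = 5.74e-07), with TOMM40 (9.96) and TIMM13 (9.75) highest. DEAD-box helicase genes were bound at 22 of 37 (Fisher adjusted p = 2.46e-08), with DDX31 (13.3) and DDX54 (10.4) highest, and 10 were kept in 3A (adjusted p = 0.0212). None of the tests of families kept in 3A, coding or non-coding, was stratified by WT fold or background. NADH dehydrogenase subunit genes (16 of 46, Fisher adjusted p = 0.00551) and exosome subunit genes (5 of 10, adjusted p = 0.027) also passed. Olfactory receptor genes were bound at 2 of 392 (Fisher adjusted p = 2.29e-27) and keratin genes at 1 of 55 (adjusted p = 0.00244). The 2 olfactory hits, OR3A2 and OR1R1, had the same WT fold (6.41) and 3A fold (3.91). Neighbouring genes of these families were counted as independent in the p-values. Collagen genes were bound at 1 of 44 (Fisher adjusted p = 0.0133). Proteasome, ATP synthase, zinc finger, homeobox cluster, solute carrier, snoRNA and microRNA genes did not pass (Fisher adjusted p from 0.0755 to 0.344). By chromosome, 48 of 186 WT peaks on chromosome 20 (25.8%, Fisher adjusted p = 0.00222) and 43 of 183 on chromosome 22 (23.5%, adjusted p = 0.0164) had a 3A peak, against 2 of 73 on X (2.74%, adjusted p = 0.0156). The median recovered background at WT peaks was 16.9 on chromosome 20, 18.0 on 22 and 8.70 on X, against 13.05 over all WT peaks.

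The mutant lists were shorter than the WT list. If the recovered background scales with IP depth, lower depth would lower it at sites shared by both lists. The median ratio there was 1.14 for 3A over WT (194 summits within 20 bp) and 1.10 for 7A over WT (13 summits). On that premise the ratios argue against lower depth in either mutant, for 7A on 13 summits only. The premise itself was not tested, since the control and any scaling behind the background are not given. Held to the lowest −log10 q of the 3A list, WT kept 4746 peaks, which argues against a stricter q-value on 3A, though filters other than on q were not tested. A lower amount of mutant protein, a lower IP efficiency and weaker binding of the mutant proteins were not tested and stay open.

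WT peaks with a 3A peak had a higher recovered background, at a median of 16.9 against 12.6 (permutation p = 1e-05, the smallest possible). Among WT peaks in the highest of 4 ranges of fold, the share with a 3A peak was 11.6% in the lowest of 4 ranges of background and 60.7% in the highest. Whether greater detection power under an even loss could account for this was modelled with a single loss factor. Averaged over the ranges of fold, the model gave 0.82 times the observed difference with the detection threshold at the 5th percentile of the −log10 p of 3A peaks. It gave 0.86 times at the 25th and 0.68 times at the lowest value. The criterion was 0.8 and the threshold was not fixed beforehand, so this average does not tell detection power and site preference apart. The model also missed the shape, giving 0.625% where 15.1% was seen for weak peaks at high background and 85.4% where 60.7% was seen for strong ones.

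Ribosomal protein genes were kept in 3A more often than other WT-bound genes. Stratified by both WT fold and background, the common odds ratio was 5.58 (3.05 to 10.2), which argues against stronger WT peaks and a higher background as the whole cause. An even loss predicted 28.7 kept genes where 42 were seen, and 29.6 and 25.5 under the other thresholds, which argues against it, although the same model predicted 24.8 nucleolar ribosome biogenesis genes where 14 were seen and so errs in both directions. A preference of 3A for sites at ribosomal protein genes may be involved, a hypothesis found and tested on the same data. Cytosolic ribosomal protein genes were also bound more often than other genes in the 7A list, at 5 of 79, so the pattern is not confined to 3A. IP signal at these genes without MYC could not be set apart, since no uninduced peak list was used. Other technical sources, among them GC content and differences between the libraries behind each list, were not tested.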
